A study of Homo sapiens with 4 samples.

How the data were processed

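Total RNA was extracted from K562 cells with Trizol and column purification, and libraries were made by Illumina protocols, per the labels. Processing of the reads with CASAVA 1.8.2 and the genome build hg18 are named in the submitters' processing notes; the aligner, the counting tool and the gene annotation are not given in the sources used here. Per library, the authors deposited read counts per gene and read counts per exon, as whole numbers that were not normalized. For all 20848 listed genes the deposited gene count equalled the sum of the gene's exon counts. Of 206550 listed exons, 1005 had coordinates listed under more than 1 gene and 0 of those held a count; 3552 exons overlapped an exon of another gene, 2043 of them on the opposite strand, and overlapping exons held 2.40% of all counts. Whether counting used strand is not given in the sources used here, so counts of overlapping genes are uncertain. The authors also deposited a table of changed genes and a table of changed exons, each with counts summed over the libraries of a group, a ratio of knockdown to control and a p-value from a test that is not given in the sources used here. In all 1470 gene rows and 93 exon rows the deposited counts equalled the sums of the per-library counts. The deposited ratio of a gene was the pooled count over the group total, within 1% in 1458 rows, and the deposited ratio of an exon was the odds of the exon against the rest of its gene, within 1% in 89 rows. Coordinates are those of the files, written 1-based.

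Libraries were grouped by the genotype and title in the labels, 2 control and 2 WTAP knockdown. The depth ran from 21002797 to 25523947 counts. The controls differed by slightly more than sampling noise in a chi-square test of genes with at least 20 counts and were kept as 2 libraries. The main comparisons, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined.

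Gene counts were filtered with filterByExpr, scaled with TMM factors and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, in R 4.3.3) on all 4 libraries, with Benjamini-Hochberg adjustment over 14760 genes and a threshold of 0.05. Standard errors of log2 fold changes are the fold change over the square root of the F statistic. The prior degrees of freedom were 2.62 beside 2 residual ones. CPM values use the TMM-scaled library sizes, and log2 CPM a prior count of 2.

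Of 23 gene lists, 22 were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists: m6A writer complex, m6A erasers and readers, erythroid, megakaryocytic, myeloid and monocytic, leukaemia stem cell and proto-oncogenes, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and p53-pathway targets, apoptosis regulators, SR proteins and splicing regulators, interferon-stimulated, heat shock and chaperones, unfolded protein and ATF4 response, mTOR and PI3K-AKT components, ribosomal proteins, replication-dependent histones, immediate early and AP-1, cholesterol synthesis and uptake, glycolysis and hypoxia, and markers of lymphoid and of fibroblast, endothelial and epithelial cells. The mitochondrially encoded list was not analysed here. Symbols of the files were matched to newer ones; CSF2RA, SRSF10, PSMB8, PSMB9, TAP1, HSPA1A, HSPA1B, RPS18 and IER3 were not analysed here. camera with an estimated correlation called 0 lists (smallest adjusted p = 0.474), fry called 10 on direction and all 22 on change in either direction.

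Exon counts were filtered with filterByExpr, and exons of genes with at least 2 kept exons were tested with edgeR's diffSpliceDGE (Simes p per gene, and p per exon). Exons were numbered from the 5′ end in the order of the files. A listed exon is a region of the files' gene model, so it may join exons of several transcripts.

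The named genes are WTAP; the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM in the higher group and both knockdown libraries on the same side of both controls; in each list up to 3 called genes with the smallest adjusted p; METTL3, METTL14, MYC, CCNA2, GATA1 and HBG1 whatever their result; the 5 genes with the smallest Simes p for exon usage whose exon moved alike in both knockdown libraries; and, in the authors' tables, the 3 largest rises, the 3 largest falls and the 3 exons with the smallest p. Entries of the authors' gene table with a count of 0 in a group were left out of this choice after the table was seen, since their ratio has no finite value. Some results of genes under this rule are not reported here.

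Alternatives were other scaling factors (RLE, upper quartile, library size only), no low-count filter or a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, each library left out, the replicate number as a block, an absolute log2 fold change of at least 1, camera with an estimated correlation, fry, other exon filters (10 summed counts, a mean of 20 counts), limma diffSplice and the gene-level F test. With a library left out a group has 1 library, which is then assumed to vary like the other group. Added after the data were seen were the sum of both controls as 1 sample, offsets for GC content and length (splines with 5 degrees of freedom each, GC content of transcripts of GENCODE release 29 matched by symbol for 96.2% of tested genes) and counts without chromosome blocks. Blocks were searched in 274 windows of 40 neighbouring genes with a mean of at least 5 CPM, against 1000 shuffles of the gene order. Ratios of genes with few counts carry exact binomial intervals at 95%, which cover counting error only.

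The scripts were tested on simulated counts drawn from the real means and library sizes. Both groups had the same common dispersion (0.0238 for genes and 0.0187 for exons). The simulated shares therefore do not cover the wider spread of the knockdown libraries. For the gene comparison (14570 genes), 60.8% of 2-fold and 98% of 4-fold changes were recovered, with 2 false calls; with the controls summed (14718 genes) 38.4% and 97% were. For exon usage (98718 exons), 39.4% of 2-fold and 86% of 4-fold changes were recovered, and 9 of 142 called genes had no changed exon. Tables were joined with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1, and figures drawn with matplotlib 3.10.9.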

Results

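Total RNA of K562 cells was sequenced in 2 control libraries and in 2 libraries of cells with WTAP knocked down. K562 is an established human cell line from a chronic myeloid leukaemia in blast crisis that carries the BCR-ABL1 fusion and lacks functional p53. WTAP is a regulatory subunit of the RNA methyltransferase complex that writes N6-methyladenosine (m6A). The series asks, by its title, about a part of WTAP in acute myeloid leukaemia; the means of the knockdown is not given in the sources used here. The deposited gene counts summed to 21002797 and 21143279 in control libraries 1 and 2 and to 22440604 and 25523947 in knockdown libraries 1 and 2, over 20848 listed genes. A count above 0 was found for 17685 and 17676 genes in the controls and for 17104 and 17381 genes in the knockdown libraries. EEF1A1, a translation elongation factor, held the largest share of counts, between 2.31% and 2.42%, in each library.

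The control libraries were nearly alike and the knockdown libraries were not. Over 14726 genes the chi-square per degree of freedom between the controls was 1.28 (p = 9.42e-112), and over 14316 genes it was 44.4 between the knockdown libraries. Among genes with at least 200 counts, the median absolute log2 difference was 0.05 between the controls, where 0 of 11157 genes lay over 2-fold apart, and 0.20 between the knockdown libraries, where 407 of 11033 did. The labels do not say that the replicates came from separate cultures, so each p-value below measures only the spread between these libraries. That spread may be technical, above all between the controls, and each test pools 2 groups of unlike spread. The sequencing lanes recorded with the files differed between the groups, so lane and group cannot be told apart.

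WTAP itself was measured first. WTAP (chromosome 6, 160068142 to 160097341, plus strand, genome build hg18) had 2093 and 2199 counts in the controls and 842 and 756 in the knockdown libraries. Its level was 97.3 ± 2.97 CPM in controls and 35.2 ± 6.49 CPM in knockdown cells (SD, n = 2 each), a log2 fold change of −1.47 (SE 0.15, edgeR adjusted p = 0.0139). The fall was uneven along the gene. Exons 1 to 7 together stood at 15.4% of the control level, and exons 8 and 9 at 66.5%. Exon 7 held most of the counts of exons 1 to 7 and stood at 14%. Exon 1 stood at 33.4%, exon 6 at 25.9%, and exons 2 to 5, with at most 66 counts in a library, between 0% and 16.9%. Exon 7 (160089213 to 160090443, 1231 nt) had 964 and 1006 counts in the controls and 123 and 163 in the knockdown libraries. Exon 9 (160096050 to 160097341), the last listed exon, had 810 and 820 against 615 and 491. Without control library 1 or 2 the WTAP fold change was −1.49 or −1.44 and no longer passed the test (adjusted p = 0.144 and 0.157).

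**Figure D1:**
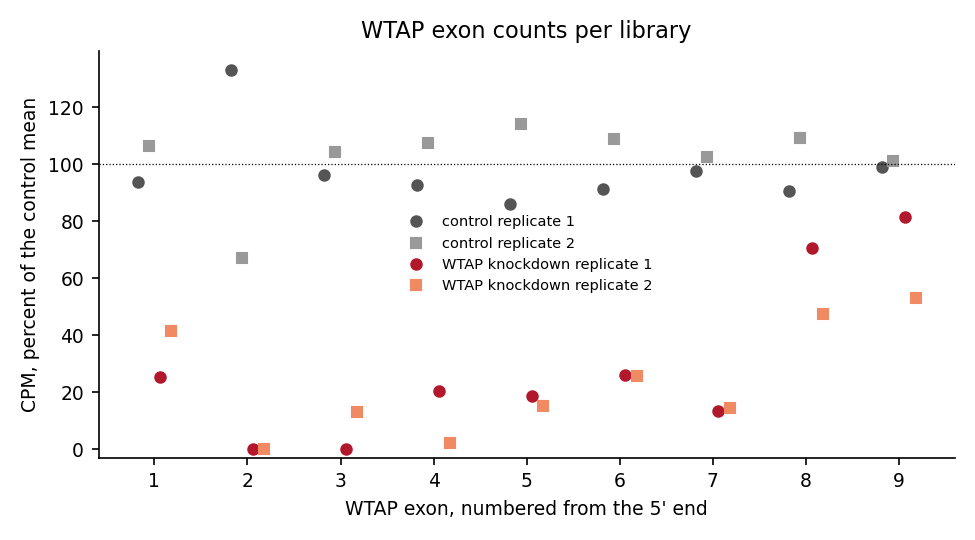
CPM of each WTAP exon as a percent of the mean of the 2 control libraries, per library, with exons numbered from the 5′ end; exon 2 had 12 and 6 counts in the controls and 0 in both knockdown libraries. In the knockdown libraries exons 1 to 7 stood at 15.4% of the control level together, and exons 8 and 9 at 66.5%.

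The question of the main comparison was which genes differ between WTAP knockdown and control cells. The changes are ranked among called genes with a mean of at least 10 CPM in the higher group, which leaves out genes such as IPW (−7.87). The largest rises were in MOBKL2B, a member of the MOB family of kinase activators (log2 fold change 6.85, SE 0.47; 0.34 ± 0.16 CPM in controls and 39.8 ± 14.9 CPM in knockdown cells, SD, n = 2 each), and in NNMT, nicotinamide N-methyltransferase (5.02, SE 0.30). The drug efflux transporter ABCG2 (4.93, SE 0.96), the acid phosphatase ACP5 (4.68, SE 0.31), the mucin MUC4 (4.30, SE 0.30), cytochrome b5 CYB5A (3.95, SE 0.17), the growth factor PDGFA (3.88, SE 0.38) and the inflammatory caspase CASP4 (3.84, SE 0.22) followed. The largest falls were in TRIM67, with 411 and 387 counts in controls and 2 and 0 in knockdown libraries, which is 0.22% of the control level (95% exact counting interval 0.0266% to 0.798%), and in the tight junction protein CLDN11 (37.8 ± 0.13 CPM in controls and 0.45 ± 0.17 CPM in knockdown cells, log2 fold change −6.41, SE 0.24). The testis serine protease PRSS50 fell by 6.17 (SE 0.17), the folate enzyme ALDH1L1 by 5.49 (SE 0.29), alpha-fetoprotein AFP by 5.49 (SE 0.37), the Rac regulator ELMO1 by 4.85 (SE 0.30) and the interleukin receptor IL1RL1 by 4.66 (SE 0.52) on the log2 scale. The cationic amino acid transporter SLC7A3 went from 15.6 ± 1.09 to 0.24 ± 0.07 CPM. The adjusted p of these 16 genes lay between 0.00813 and 0.0332. The ranking took only genes with both knockdown libraries on the same side of both controls, so that trait is no added support. ABCG2 differed between the knockdown libraries (527 and 146 counts) and did not pass with limma-voom. TRIM67 and ELMO1 lie in chromosome blocks whose genes shifted together in at least 1 knockdown library.

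**Figure D2:**
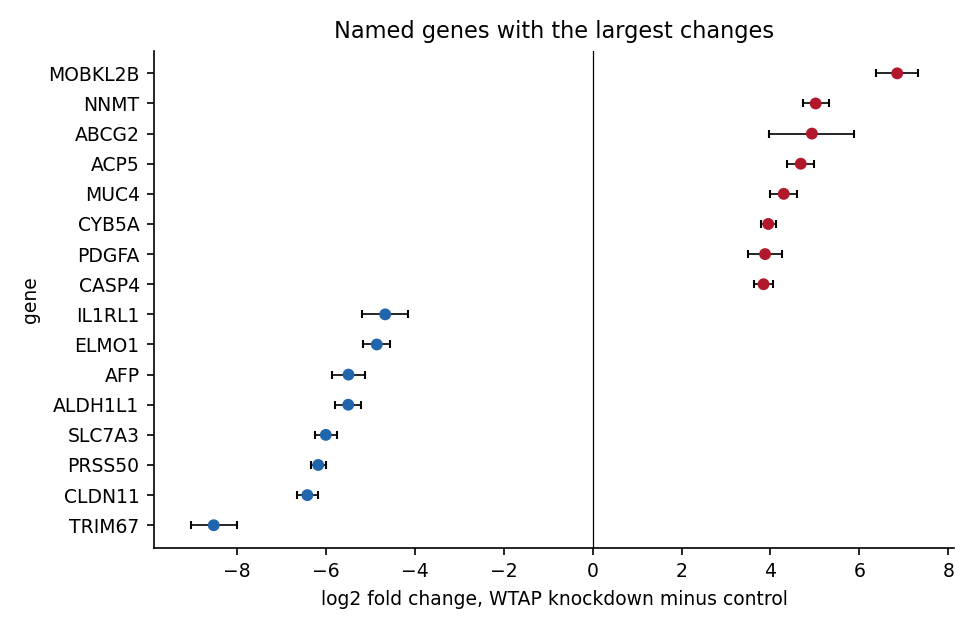
Log2 fold change (WTAP knockdown minus control) of the 8 genes with the largest rise and the 8 with the largest fall under the fixed rule; points are edgeR estimates and bars ± 1 SE, over 2 libraries per group. MOBKL2B rose by 6.85 and CLDN11 fell by 6.41 on the log2 scale.

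In all, 3119 of 14760 tested genes changed at an adjusted p below 0.05 in edgeR's quasi-likelihood test, 1767 higher and 1352 lower. At least a 2-fold change was estimated for 1109 of them, 380 higher and 729 lower. Without a test, 299 genes lay at least 2-fold above the control mean in both knockdown libraries and 773 lay at least 2-fold below. The split of the calls hung on the scaling: 1141 were higher and 1921 lower with upper-quartile factors, and 1086 higher and 1991 lower with library size only, which moved the median of all genes by −0.12 and −0.13 log2. The calls also rest on the closeness of the controls: with control library 1 or control library 2 left out, edgeR called 0 genes, with 2264 and 2255 at an unadjusted p below 0.05, whereas 9723 and 10003 passed without knockdown library 1 or 2.

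Among the gene groups fixed beforehand, cholesterol synthesis and uptake genes moved up. Of 26 tested genes 14 rose and 0 fell (17 higher adjusted over the list alone), with a median log2 fold change of 0.65. MVD, the mevalonate decarboxylase, rose from 66.0 ± 2.75 to 133.2 ± 1.83 CPM (log2 1.01, SE 0.07), FDPS, the farnesyl diphosphate synthase, by 0.81 (SE 0.07), and HMGCS1, which makes HMG-CoA, by 0.78 (SE 0.07). The list differed from the other genes by camera (adjusted p = 6.73e-06; adjusted p = 0.474 with an estimated correlation). Of 38 genes of the unfolded protein and ATF4 response, 15 rose and 0 fell (21 higher adjusted over the list alone; median 0.44; camera adjusted p = 3.17e-05; adjusted p = 0.474 with an estimated correlation). The amino acid transporter subunit SLC3A2 rose by 0.76 (SE 0.09), the chaperone DNAJB9 by 0.74 (SE 0.09) and the transcription factor XBP1 by 0.68 (SE 0.07).

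Erythroid genes rose in part. Of 41 tested genes 16 rose and 1, the carbonic anhydrase CA1 (named after its value was seen), fell (19 higher and 2 lower adjusted over the list alone), with a median of 0.56, which was 0.50 in knockdown library 1, 0.31 in knockdown library 2 and 0.29 after the GC and length correction (camera adjusted p = 0.00227; adjusted p = 0.474 with an estimated correlation). The fetal globin HBG2 went from 154.7 ± 0.55 to 402 ± 23.9 CPM (log2 1.38, SE 0.08) and HBG1 from 115.7 ± 2.37 to 279 ± 11 CPM (log2 1.27, SE 0.08); these copies are nearly identical, and counts may be split between them. The membrane glycoprotein GYPC rose by 1.45 (SE 0.12). GATA1, the master transcription factor of the lineage, did not pass (log2 0.10, SE 0.10, adjusted p = 0.519); its direction turned with upper-quartile factors, library size only, the GC and length correction and without knockdown library 2, and it passed without knockdown library 1 (log2 0.21).

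CDK inhibitors and p53-pathway targets rose in 9 of 25 genes and fell in 0 (9 higher adjusted over the list alone; median 0.38, which was 0.25 with library size only and 0.24 after the GC and length correction; camera adjusted p = 0.00278; adjusted p = 0.474 with an estimated correlation). TP53INP1 rose by 1.17 (SE 0.08), FDXR by 0.85 (SE 0.08) and the BH3-only gene BBC3 by 0.92 (SE 0.12) on the log2 scale. Of 30 apoptosis regulators, which share BBC3 with that list, 11 rose and 1, BIRC3 (named after its value was seen), fell (12 higher and 1 lower adjusted over the list alone; median 0.24, which was 0.12 with upper-quartile factors and 0.11 with library size only; camera adjusted p = 0.00398; adjusted p = 0.474 with an estimated correlation). The caspase inhibitor XIAP rose by 0.49 (SE 0.07). BBC3 did not pass after a correction for GC content and length.

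Ribosomal protein genes were higher as a group by a small amount. Of 73 tested genes 11 rose and 0 fell (7 higher adjusted over the list alone), with a median of 0.26, which was 0.36 in knockdown library 1 and 0.15 in knockdown library 2, 0.14 with upper-quartile factors, 0.12 with library size only and 0.16 after the GC and length correction (camera adjusted p = 7.46e-07; adjusted p = 0.786 with an estimated correlation; fry adjusted p = 0.175). RPL35 (0.85, SE 0.08) and RPL7A (0.84, SE 0.10) lie in a block of chromosome 9 whose genes were higher together, and 38.3% of the RPL35 counts are in exons that overlap another gene; outside the blocks 8 of 70 rose, among them RPL29 (0.58, SE 0.09). Short and GC-rich genes were higher in the knockdown libraries at large: the median log2 fold change went from 0.18 in the 10% of genes with the shortest exonic length to −0.17 in the 10% with the longest, and from −0.10 in the 10% lowest in GC content to 0.27 in the 10% highest. Genes matched to the ribosomal protein genes in level, GC content and length had a median of 0.31, against 0.26 for the ribosomal protein genes (difference −0.05, 95% bootstrap interval −0.10 to 0.03). The match was loose: 95 different genes served, many more than once, at a median level of 9.88 log2 CPM against 10.28. The interval takes no account of shared matches and may be too narrow.

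Markers of lymphoid cells, fixed as signs of another cell type, were lower. Of 8 tested genes 4 fell and 0 rose (4 adjusted over the list alone; median −0.97; camera adjusted p = 0.00704; adjusted p = 0.474 with an estimated correlation, and adjusted p = 0.0767 without knockdown library 2). The T-cell receptor complex gene CD3D fell from 29.1 ± 1.03 to 6.99 ± 0.55 CPM (log2 −2.06, SE 0.13), CD3G by 2.47 (SE 0.25) and CD4 by 1.60 (SE 0.30). CD4 had at most 40 counts in a library and did not pass with DESeq2. The tested markers, 8 of 16 listed, had a mean of 4.55 CPM. After the GC and length correction, 3688 genes below 5 CPM outside the chromosome blocks lay at −0.38 and −0.35 in knockdown libraries 1 and 2. camera compares the list with genes of all levels, so it does not part the list from this fall of low-level genes. Of 14 markers of fibroblast, endothelial and epithelial cells, 3 rose and 2 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.511). EPCAM, an epithelial adhesion molecule, rose by 0.88 (SE 0.17), COL6A3, a collagen chain, rose by 0.60 (SE 0.11) and ESRP1, an epithelial splicing regulator, fell by 2.37 (SE 0.41). COL6A3 did not pass with library size only.

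**Figure D3:**
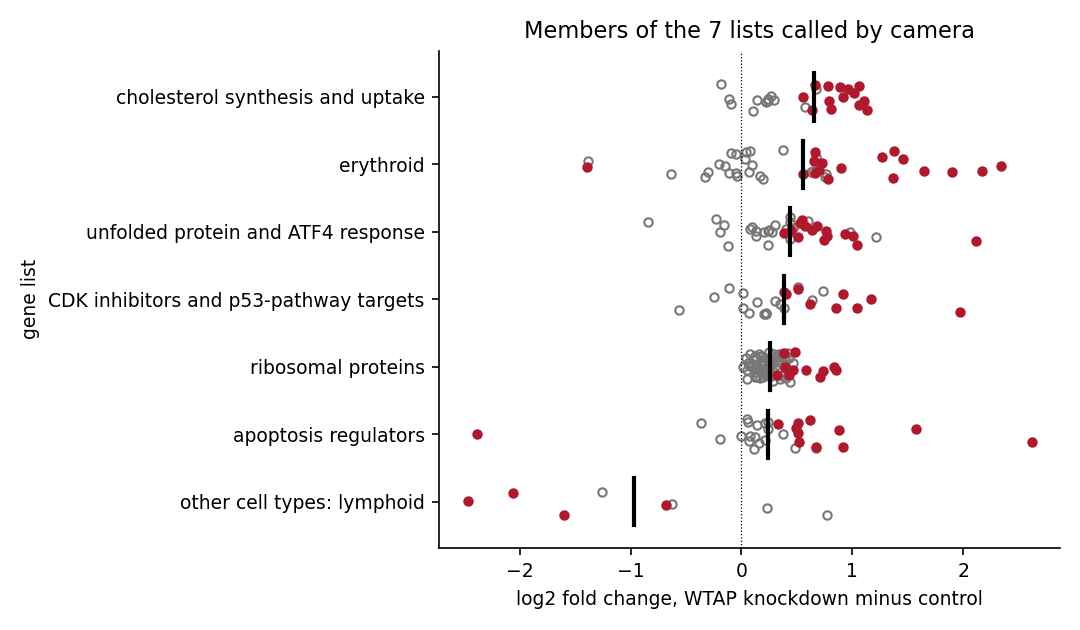
Log2 fold change (WTAP knockdown minus control) of each tested member of the 7 lists called by camera; filled points are genes called by edgeR at an adjusted p below 0.05, open points are genes not called, and black lines are list medians. The medians run from −0.97 for lymphoid markers to 0.65 for cholesterol synthesis and uptake.

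The other 15 tested lists did not pass camera. In the m6A writer complex (8 genes; camera adjusted p = 0.818), WTAP fell and RBM15, an RNA-binding subunit, rose (0.53, SE 0.10), the same count adjusted over the list alone. The catalytic subunit METTL3 had a log2 fold change of −0.32 (SE 0.10, adjusted p = 0.0782) and its partner METTL14 −0.12 (SE 0.11, adjusted p = 0.456), neither of which passed; METTL3 passed with upper-quartile factors, with library size only and without either knockdown library, and METTL14 without knockdown library 2 (log2 −0.23). Of 14 erasers and readers (camera adjusted p = 0.511), the demethylase ALKBH5 rose (0.44, SE 0.09; 0 genes adjusted over the list alone). RBM15 and ALKBH5 did not pass with upper-quartile factors or library size only, nor ALKBH5 after the GC and length correction.

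Cell-cycle lists moved both ways. Of 35 genes of G1/S and DNA replication, 6 rose and 4 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.817), with a median of −0.07, which was −0.09 in knockdown library 1, −0.03 in knockdown library 2, −0.19 with upper-quartile factors and −0.21 with library size only, and a mean of 0.04. The G1 cyclin CCND1 rose from 9.29 ± 0.98 to 39.8 ± 7.79 CPM (log2 2.10, SE 0.19), the licensing factor CDT1 rose by 0.71 (SE 0.07), and the polymerase clamp PCNA fell by 0.55 (SE 0.07; log2 −0.55). Of 32 genes of G2/M and mitosis, 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.219, and it passed without knockdown library 1 with adjusted p = 0.0325). CENPA, a centromere histone, rose by 0.66 (SE 0.09), the cyclin CCNB1 by 0.65 (SE 0.09) and the transcription factor FOXM1 by 0.56 (SE 0.08). CCNA2 passed narrowly (0.45, SE 0.10, adjusted p = 0.0455), with 44.2% of its counts in exons that overlap another gene, and it did not pass with upper-quartile factors, library size only, no low-count filter, a filter at 1 CPM or the replicate number as a block.

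Lineage and oncogene lists held changes in either direction. Of 25 myeloid and monocytic genes 4 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.642): CD68 rose by 1.05 (SE 0.11), the transcription factor SPI1 rose by 0.85 (SE 0.09), and the receptor CSF1R fell by 2.27 (SE 0.31). The median of this list was 0.20 (0.52 in knockdown library 1 and −0.20 in knockdown library 2; 0.08 with upper-quartile factors, 0.06 with library size only and 0.12 after the GC and length correction), the mean 0.08, and the direction by fry was down (adjusted p = 0.931). Of 17 megakaryocytic genes 4 rose and 2 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.668); PDGFA was among the rises, and GFI1B, a repressor that lies in the chromosome 9 block, fell by 0.58 (SE 0.09). Of 23 leukaemia stem cell genes and proto-oncogenes 6 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.325, and adjusted p = 0.0469 without knockdown library 2). The homeobox gene MEIS1 rose by 1.06 (SE 0.16), LMO2 by 0.72 (SE 0.12) and CCND2 by 0.58 (SE 0.11), the last of these not with upper-quartile factors or library size only. MYC did not pass (log2 −0.08, SE 0.08, adjusted p = 0.491), though it did without knockdown library 1.

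Stress, signalling and metabolic lists were mixed. Of 32 interferon-stimulated genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.03, which was −0.08 in each knockdown library; camera adjusted p = 0.758; fry adjusted p = 0.0208). ISG15, a ubiquitin-like modifier, rose by 2.10 (SE 0.16), IFITM2 by 1.53 (SE 0.09) and IFITM1 by 1.32 (SE 0.07). Of 23 heat shock genes and chaperones 1 rose and 4 fell (1 and 4 adjusted over the list alone; median 0.02, which was −0.02 in knockdown library 1 and −0.07 in knockdown library 2, mean −0.06; camera adjusted p = 0.668; fry adjusted p = 0.00401). The chaperone HSP90AB1 fell by 0.42 (SE 0.07) and FKBP4 by 0.36 (SE 0.07), while the heat shock factor HSF1 rose by 0.48 (SE 0.08). Of 33 glycolysis and hypoxia genes 7 rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.511, and adjusted p = 0.0488 without knockdown library 1); the glucose transporter SLC2A1 rose by 0.95 (SE 0.08), VEGFA by 0.70 (SE 0.07) and the hexokinase HK2 by 0.69 (SE 0.08). Of 29 mTOR and PI3K-AKT components 5 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.143; fry adjusted p = 0.0234). MLST8 rose by 0.78 (SE 0.08), with 33.1% of its counts in exons that overlap another gene, and TSC1, in the chromosome 9 block, rose by 0.74 (SE 0.11).

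Of 35 replication-dependent histone genes 7 rose and 0 fell (7 adjusted over the list alone; median 0.20, which was 0.09 with upper-quartile factors, 0.07 with library size only and 0.08 after the GC and length correction; camera adjusted p = 0.0593). HIST2H2AC rose by 1.39 (SE 0.10), HIST1H2BC by 1.10 (SE 0.18) and HIST1H1C by 1.04 (SE 0.12); the list passed camera under 8 alternatives, with an adjusted p between 0.0165 and 0.0496, and not after the GC and length correction. These genes have near copies. Of 28 immediate early and AP-1 genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.143). KLF4, in a second block of chromosome 9, rose by 1.98 (SE 0.32), FOSL1 by 0.69 (SE 0.12) and JUND by 0.54 (SE 0.08). Of 35 SR proteins and splicing regulators 3 rose and 0 fell (1 adjusted over the list alone; camera adjusted p = 0.143): SFRS4 by 0.61 (SE 0.07), HNRNPF by 0.54 (SE 0.12) and CLK1 by 0.50 (SE 0.11). After the GC and length correction FOSL1, JUND, HSF1, MLST8 and CLK1 did not pass; HNRNPF and CLK1 did not pass with upper-quartile factors, library size only or no low-count filter, and HSP90AB1 and FKBP4 did not with the replicate number as a block. The medians of the lists for m6A writers, m6A erasers and readers, G2/M, SR proteins, interferon-stimulated genes, heat shock, and glycolysis and hypoxia were above 0 and lay below 0 with library size only. Each of the 76 called genes under the rule for named genes, WTAP aside, kept its direction under each alternative run, and 0 of the 76 passed without control library 1 or control library 2.

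Exon usage was compared to ask which exons changed relative to the rest of their gene. TEX11, a meiosis gene, fell from 412 and 414 to 55 and 60 counts, while its exon 3 (chromosome X, 70034040 to 70034161) kept 33 and 42 against 27 and 36 counts; the share of that exon went from 9.08% ± 1.51 to 54.5% ± 7.71 of the gene's counts (SD, n = 2 each; relative log2 change 1.75, SE 0.21, adjusted p = 9.02e-06). Exon 3 of GLUL, glutamine synthetase (chromosome 1, 180626255 to 180626610), went from 0.43% ± 0.02 to 0.14% ± 0.04 (−1.15, SE 0.12, adjusted p = 1.8e-05). Exon 3 of the reticulon gene RTN3 (chromosome 11, 63242750 to 63245080, 2331 nt) went from 2.29% ± 0.35 to 0.70% ± 0.16 (−1.18, SE 0.13, adjusted p = 9.92e-05). Exon 38 of the cytoskeletal linker MACF1 (chromosome 1, 39569397 to 39574912, 5516 nt) went from 2.21% ± 0.16 to 0.82% ± 0.19 (−0.99, SE 0.15, adjusted p = 0.000672). Exon 10 of the inhibitor-of-apoptosis gene BIRC6 (chromosome 2, 32493341 to 32494735, 1395 nt) went from 2.20% ± 0.31 to 0.57% ± 0.16 (−1.36, SE 0.23, adjusted p = 0.00268). WTAP exon 7 passed as well, from 45.9% ± 0.22 to 18.1% ± 4.92 (−0.96, SE 0.15, adjusted p = 0.021).

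Of 10802 tested genes, 11 had a changed exon by edgeR's diffSpliceDGE with Simes p-values, and 11 of 101711 exons passed alone, 9 lower and 2 higher. These sets differ by DPY19L2 and RNF213, named after their values were seen. DPY19L2 passed as a gene while its exon did not (exon-level adjusted p = 0.0583). An exon of RNF213 passed (exon-level adjusted p = 0.0496) while the gene did not (Simes adjusted p = 0.149). At an unadjusted Simes p below 0.05 there were 365 genes, where evenly spread p-values would give 540. Simes p-values need not be evenly spread without a change, so this shortfall is no test of the count of 11 genes. The count was 100 with limma diffSplice, 242 with edgeR's gene-level F test, 0 without control library 1 or control library 2, 433 without knockdown library 1 and 1576 without knockdown library 2.

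The authors' own comparison of the same libraries was set beside these calls. In the authors' deposited table of genes, MOBKL2B had the largest ratio of knockdown to control, 109, from 1860 against 15 pooled counts. MDGA2 had a ratio of 94.0 in the authors' deposited table, from 107 against 1 pooled counts (95% exact counting interval of the ratio 16.5 to 3748). Of the 107 counts, 102 were in knockdown library 1 and 5 in knockdown library 2. Like PRG3, MDGA2 was not tested here, since the low-count filter left out genes above its cutoff in 1 library only. PRG3 had a ratio of 70.7 in the authors' deposited table, and its 161 pooled counts were 2 in knockdown library 1 and 159 in knockdown library 2 (interval 19.3 to 589.1). The smallest ratios with a count in each group in the authors' deposited table were those of TRIM67 (0.00221), the imprinted non-coding gene IPW (0.00313, from 1 against 282 pooled counts, interval 7.86e-05 to 0.0175) and CLDN11 (0.0105).

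The authors' deposited table listed 1470 genes, 390 with a ratio above 1 and 1080 below 1, each at least 2-fold from 1 and each with a p of at most 9.96e-06. Of the 1452 that were tested here, all 1452 had the direction of the authors' ratio and 1029 (70.9%) were called. At an adjusted p below 0.01 the calls here fell from 3119 to 62 genes in all, and each of the 62 is in the authors' deposited table. In both knockdown libraries separately 1024 of the 1470 (69.7%) lay over 2-fold from the control mean in one direction, and for 35 the knockdown libraries lay on opposite sides of it. The authors' deposited table of exons listed 93 exons of 76 genes. Its smallest p-values were those of WTAP exon 9 (ratio 3.67), WTAP exon 7 (ratio 0.257) and an exon of C1orf103 (chromosome 1, 111295433 to 111296960; ratio 0.436). Of the 82 exons tested here all 82 had the direction of the authors' ratio, and 11 were called, 5 of them at an adjusted p below 0.01; of the 3 named here, WTAP exon 7 alone was called (exon 9, adjusted p = 0.334; C1orf103, adjusted p = 0.232). The same libraries underlie both analyses, so this overlap is no independent evidence.

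**Figure D4:**
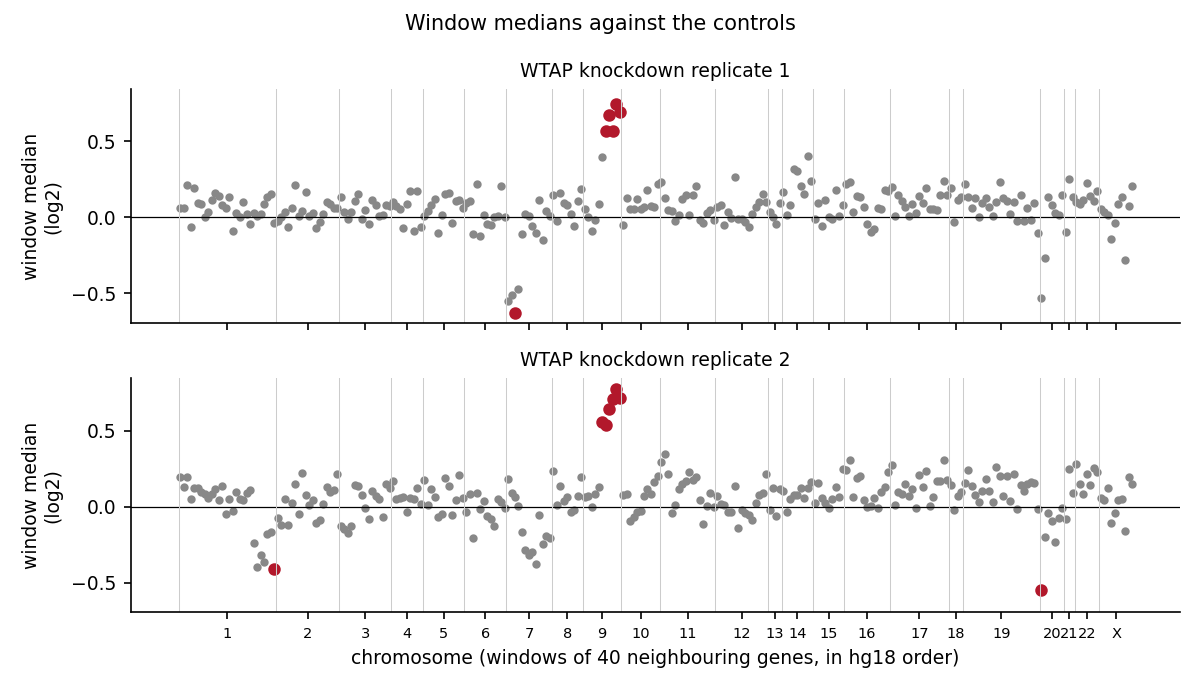
Median log2 difference from the control mean, after correction for GC content and length, in windows of 40 neighbouring genes along the chromosomes (hg18 order), for knockdown libraries 1 and 2; red points lie beyond every one of 1000 shuffles of the gene order. The end of the long arm of chromosome 9, from 117955892 to 139850397, stood above 0 in both knockdown libraries, with block medians of 0.62 and 0.69.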

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

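The sum of the controls, the GC and length correction and the count without chromosome blocks were chosen after the data were seen. WTAP kept its direction under each of 14 alternatives, from −1.28 without knockdown library 2 to −1.66 without knockdown library 1; it did not pass with the controls summed (−1.46, adjusted p = 0.138) or without control library 1 (−1.49) or 2 (−1.44). The count of changed genes, 3119, lay between 2492 and 3364 under 10 alternatives, was 1109 with a log2 fold change of at least 1, ranged from 0 to 10003 with a library left out, and was 0 in edgeR with the controls summed (2344 at an unadjusted p below 0.05; the same simulated test recovered 97% of 4-fold changes). Leaving out or summing controls takes 1 of the 2 close control libraries away, so the spread is set by the knockdown libraries. Leaving out a knockdown library sets it by the controls. The simulated counts had the same dispersion in both groups. The 97% therefore does not tell what the test recovers at the spread of the knockdown libraries. camera called between 7 and 9 lists with a library left out and 0 with an estimated correlation.

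The replicate number as a block gave 2745 changed genes, 2370 of them shared with the unblocked 3119, and 4 genes in place of 11 with changed exon usage. The labels do not say that a number marks a shared batch, and the deviations of same-numbered libraries correlated at −0.001 across genes. For exon usage the count of 11 genes became 9 and 8 under the other exon filters, 100 with limma diffSplice and 242 with the gene-level F test. It was 0 with the controls summed, and ranged from 0 to 1576 with a library left out. Each fit with a library left out had equally many libraries, so a lower number of samples alone cannot account for that range. The cause of these differences in exon usage was not tested. At an adjusted p below 0.01 the gene calls here fell from 3119 to 62, all in the authors' gene table (1029 shared at 0.05), and the exon calls from 11 to 5, all in their exon table.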

Other observations

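The search for chromosome blocks, the genes at 0 counts, the comparison of the knockdown libraries with each other, the comparison of low-level genes in the chromosome 9 block with those elsewhere and the test of called long exons were chosen after results had been seen, and the genes of this paragraph and ABL1 were chosen after their values were seen. The knockdown libraries took opposite directions for 30 genes, with 1 library at least 2-fold above the control mean and the other at least 2-fold below. KIT, the stem cell factor receptor, had 550 and 539 counts in controls, 1127 in knockdown library 1 and 301 in knockdown library 2 (log2 1.11 and −1.01). TC2N had 274 and 304 counts in controls, then 124 and 1231, and the sulfotransferase CHST3 had 155 and 150, then 666 and 28. The fold change of KIT in the group comparison was 0.40 (SE 0.68) and did not pass. At the other end, 4 genes with at least 40 counts over the controls had 0 counts in both knockdown libraries, and 0 genes showed the converse. The glutathione transferase GSTA1 (86 and 63 counts in controls) was at least 56.5-fold lower, against a floor of 3 counts over the group, transthyretin TTR (32 and 34) at least 25-fold, the glycosyltransferase UGT3A2 (33 and 29) at least 23.5-fold and FAM26F (18 and 26) at least 16.7-fold.

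Neighbouring genes also shifted together in 1 knockdown library on chromosome 7 (23603523 to 37455036, −0.62 in library 1 and 0.06 in library 2). They did so at the end of chromosome 1 (229181446 to 243094450, −0.41 in library 2). The windows of chromosome 1 from 159943386 to 229181230 were low in library 2 as well (−0.396 to −0.166), short of the largest shuffle of 0.401. In library 1 these windows lay between 0.007 and 0.156. The start of chromosome 20 (199524 to 3852502) was low in both (−0.53 and −0.55) but passed the shuffles in knockdown library 2 only. The second block of chromosome 9 (103335954 to 116920307, 0.40 and 0.55) also passed in library 2 only. Compared with each other, the knockdown libraries differed beyond all shuffles (largest 0.28) in 4 adjacent windows of chromosome 7 from 503425 to 50485582, by 0.62, 0.67, 0.72 and 0.49 higher in library 2, in 3 further windows of chromosome 7 between 72492664 and 104441824, by 0.29, 0.37 and 0.29 lower in library 2, and at the end of chromosome 1, by 0.30 lower in library 2. The blocks, which leave out windows short of the shuffles, held 204 of the 3119 called genes. No window differed by more than 0.05 between the controls. ABL1, in the largest chromosome 9 block, did not pass (log2 0.13).

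The largest of 5 chromosome blocks whose neighbouring genes shifted together held 188 searched genes of chromosome 9 from 117955892 to 139850397. After correction for GC content and length their medians were 0.62 and 0.69 log2 above the controls, against 0.76 and 0.72 before it. The search used the corrected values, so the smaller median, 0.621, had to lie far from 0 and cannot test such a bias. Of 1000 shuffles of the gene order, 0 gave a window as far out in knockdown library 1. A difference in copy number between the cell populations was tested first by the share of those genes above 0 in both libraries (93.1%), which was set aside because the genes had been picked for the shift. The test put in its place, with its prediction written before it was run, took the 51 tested genes of the block below 5 CPM: their smaller median was −0.126, where over 0.3 was predicted for a copy number change and under 0.15 without one. Taken as written that result speaks against copy number, but genes of this level elsewhere lay at −0.38 and −0.35, so the 51 lay 0.25 and 0.40 above them; this comparison, and the reading of the result as undecided, came after the result was seen, and copy number and a regional change of transcription may each account for the block.

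WTAP exons 8 and 9 fell by 2.07 log2 less than exons 1 to 7, 2.40 in knockdown library 1 and 1.74 in library 2. A loss of 5′ coverage in the knockdown libraries is argued against. The difference stood at the 99.99 percentile of 8393 genes, whose central 95% ran from −0.35 to 0.67. The split before the last 2 exons was chosen from WTAP's own exon counts and not from those of the other genes, so the percentile may be too high. Reads of an overlapping listed gene are argued against too, with 0 exons of other listed genes over exons 8 and 9 and the next gene, ACAT2, 5638 nt away. What remains open is a transcript or a read pile-up at the 3′ end that the listed exons cannot show; no biological explanation was tested, and the means of the knockdown could matter.

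Exons inside genes were lower relative to their genes at every length, from a median of −0.04 under 100 nt to −0.10 for 942 non-terminal exons of at least 1000 nt, against 0.03 for 5313 last exons of that length; first exons went from 0.03 under 100 nt to −0.13 in the longest group. The difference of −0.13 (95% bootstrap interval −0.15 to −0.11) cannot decide whether all long exons fell, so a part of length stays open. Each exon was measured against its own gene, and last exons held between 39.78% and 41.74% of all counts per library. A long last exon therefore partly sets the level it is measured against, and the contrast mixes position with length. The long non-terminal exons had a median of −0.012 from their neighbouring exons (269 exons, two-sided sign-flip permutation p = 0.2). That value goes with coverage that changed along the transcript, a change seen mainly in knockdown library 1. The median difference of the last 2 exons from the others over all genes was 0.22 there, against 0.06 in library 2 and 0.05 between the controls. Of the 9 exons called lower, 7 were non-terminal exons of at least 1000 nt, while such exons were 1.04% of those tested. These 7, in BIRC6, RTN3, WTAP, EEF1D, FAM161A, RNF213 and MACF1, of which EEF1D, FAM161A and RNF213 were named after their values were seen, had a median of −0.549 from their neighbours, from −1.33 in BIRC6 to 0.68 in MACF1. The MACF1 value rests on few counts: the adjacent exon 39 had 10 and 16 in controls and 1 and 4 in the knockdown libraries. That exon was itself lower relative to the gene (−1.67), though it did not pass. Whether coverage accounts for these 7 cannot be told apart from changed splicing, since RNF213 was hardly lower than its neighbours and the set was picked by its own calls.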
